A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

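Strand-specific RNA-seq of the fission yeast Schizosaccharomyces pombe was analysed in 4 libraries, 2 from wild type (WT) and 2 from spt6-1, a strain with a mutant allele of the transcription elongation factor and histone chaperone gene spt6. Per the labels' protocols, both strains were grown in rich medium at 30 °C and moved to 37 °C for 2 h, polyadenylated RNA was selected, adaptors were ligated to the RNA so that the strand was kept, and the libraries were read on a Genome Analyzer IIx. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples.

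Per the submitters' processing notes, reads were aligned with TopHat to the genome build ASM294v2. The counter, the source of the annotation, the handling of reads with several positions and any filter on the reads are not given in the sources used here. The deposited values are RPKM, reads per kilobase of feature scaled by a library denominator, with 1 sense and 1 antisense value per library for 7023 features. These comprise 5134 protein-coding transcripts, 1551 non-coding RNAs, 196 tRNA genes, 49 rRNA genes, 55 snoRNA genes, 7 snRNA genes and 31 pseudogenes. The lengths and denominators behind the authors' RPKM were worked out from the values. Sense RPKM divide by the summed exon length and antisense RPKM by the whole locus from start to end. The denominators were 35917252 and 17201744 reads for WT replicates 1 and 2, and 27994342 and 17272448 reads for spt6-1 replicates 1 and 2, the same on both strands. With these, 100% of the values were whole numbers of reads within a tolerance of 0.01 read. Only the denominator of WT replicate 2 was itself a whole number, and that of spt6-1 replicate 1 was 70.5% of the sense reads recovered for that library, against 98.3% to 102.2% in the other 3. A deposited list of splice junctions, whose values are genome positions rather than a measurement of any library, holds 12365 junctions, among them 5356 annotated introns of the table, and was not used for any comparison. All 38 mitochondrial features of the table are at 0 in every library.

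The recovered sense reads numbered 36520471 and 17093322 in WT and 39693042 and 16894607 in spt6-1, in the order of the replicates. Antisense reads numbered 4716866, 2231131, 5672959 and 2960923. A single read per kilobase equals 0.0278, 0.0581, 0.0357 and 0.0579 RPKM in these libraries, which sets the precision of low values. Ribosomal RNA took 12.75%, 6.43%, 17.8% and 3.73% of the sense reads.

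The comparison was spt6-1 against WT, the only groups. Values were taken as log2(RPKM + 0.5) and tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Fold changes are limma's, so they include the pseudocount, while means and standard deviations (SD) are of RPKM. The sense fit used every feature at 1 RPKM or more in at least 2 libraries. The antisense fit used protein-coding genes at 0.5 RPKM or more in at least 2 libraries. The ratio fit used the log2 antisense value minus the log2 sense value of each library for genes past both filters. For the antisense share of a library an exact two-sided permutation test was used, for which 2 against 2 libraries cannot give a p under 0.33. Replicate numbers are shared between the groups as numbers only, and no label pairs the libraries, so no replicate block was used.

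Before the data were examined, 22 gene lists were fixed, together with the rule for named genes, the tests and the main set of alternatives. The lists reported here were elongation factors and partners, histones, histone chaperones and deacetylases, heat shock chaperones, core stress response, meiotic genes, M mating type, P mating type, telomere-linked helicases and silent mating type, Tf2 retrotransposons, cytosolic ribosomal proteins, ribosome biogenesis, phosphate and thiamine repressed, iron starvation, MBF and DNA replication, glucose repressed and hexose transport, glycolysis and cytoskeleton housekeeping, RNA decay and surveillance, RNAi and heterochromatin, splicing factors, and RNA polymerase II subunits. Each list was tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all 22 lists, and on the sense strand also against protein-coding genes only, an alternative chosen after seeing the data. Camera asks whether a list's genes moved more or less than the other genes. With an estimated correlation and 4 libraries it has few degrees of freedom, so a list that does not pass there is not shown to be unchanged. The annotated classes of RNA and the position classes were tested in the same way. Subtelomeric means within 100 kb of an end of chromosome I or II.

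The named genes are spt6, the 10 protein-coding genes with the largest rise and the 10 with the largest fall per strand, up to 4 members of each list with the smallest adjusted p, the 3 non-coding RNAs with the largest rise, and the 5 largest rises and 5 largest falls of the ratio. The largest changes were taken among genes past the threshold with a mean of at least 5 RPKM (sense) or 2 RPKM (antisense) and no overlap between the values of the groups. Other features named are described as chosen after their values were seen.

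The alternatives fixed in advance were a pseudocount of 0.1 or 1, no filter and a filter 5 times as strict, median-centred libraries, quantile normalization, a replicate block, no trend, a fold change of at least 2 beside the threshold, and each library left out in turn. With a library left out its group has 1 sample, which is assumed to vary like the other group. Alternatives chosen after seeing the data were voom on the recovered reads, protein-coding genes only, genes with no annotated opposite-strand feature, antisense values scaled by the median sense change, and subtelomeric genes with a sequence found once in the genome. Copies were found with blastn 2.17.0 at 95% identity or more against the reference genome, with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and Biopython 1.88. Positions were checked against that reference, where 5121 of 5123 nuclear coding sequences of the table begin with a start codon. Figures were drawn with matplotlib 3.10.9.

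The fits were tested on simulated data made from the WT means and the spread between replicates. Of simulated sense changes, 57.3% of those of 2-fold and 99.7% of those of 4-fold were recovered, with 9.2% false calls. For antisense the values were 47.9%, 96.7% and 4.9%, and for the ratio 17.2%, 86.2% and 3.6%. The simulated fits tested 2588 antisense genes and 2496 ratios, against 4728 and 4682 in the data. Being made from WT means, the simulation leaves out many genes with antisense RNA near 0 in WT. The antisense and ratio rates are thus not shown to hold for genes that reached the filter only in spt6-1.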

Results

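RNA of 7023 annotated features was measured on both strands in 4 fission yeast libraries, 2 from WT and 2 from spt6-1, all from cells held at 37 °C for 2 h. The title of the series names the role of Spt6 in intragenic and antisense transcription, and the comparison of spt6-1 with WT asks which RNAs changed on either strand. Depth was 36520471 and 17093322 sense reads in WT replicates 1 and 2, and 39693042 and 16894607 in spt6-1 replicates 1 and 2. The median protein-coding gene had 27.1 and 28.3 sense RPKM in WT and 28.7 and 28.2 in spt6-1. Its antisense level was 0.499 and 0.465 RPKM in WT and 3.99 and 3.44 in spt6-1. Across genes, which are not independent replicates, the sense values of the replicates correlated at a Pearson r of 0.981 in WT and 0.952 in spt6-1, against 0.853 to 0.892 between the groups.

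The spt6 transcript itself (SPAC1F7.01c, chromosome I, 4212476 to 4216888, minus strand) fell from 63.5 ± 2.75 RPKM in WT to 10.5 ± 3.11 RPKM in spt6-1 (mean ± SD, n = 2 each), 5.93-fold lower with an adjusted p of 5.39e-04. At the same locus antisense RNA rose from 0.0447 ± 0.026 to 38.0 ± 17.7 RPKM, 66.9-fold higher with an adjusted p of 6.57e-07. The antisense log2 change of 6.06 was 7.97 with a pseudocount of 0.1 and 5.145 with 1. Both changes passed the threshold with each library left out. All means below are given with their SD and n = 2 per group.

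**Figure D1:**
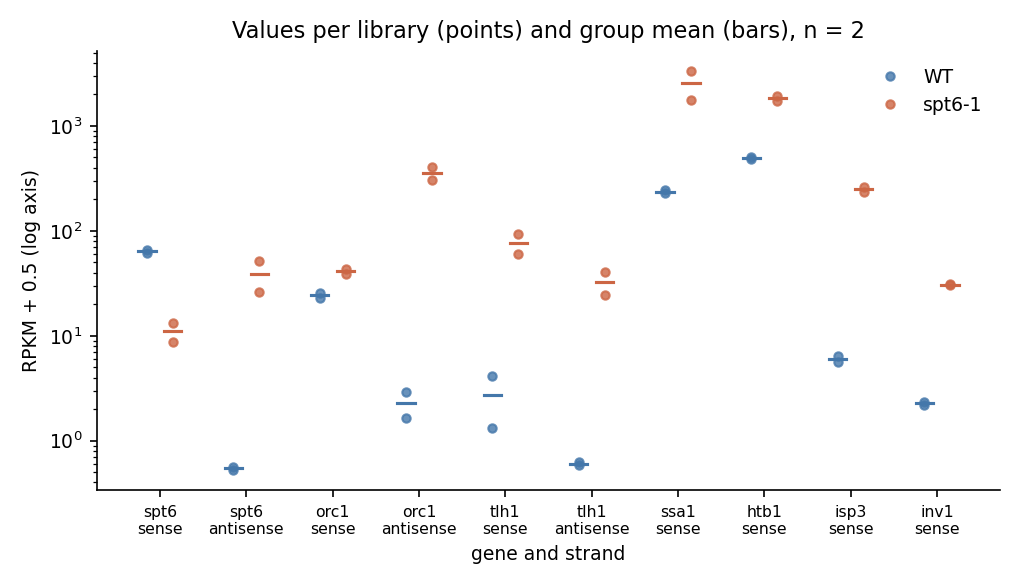
RPKM plus 0.5 on a log axis for 7 genes, with a point per library and a bar at the mean of each group (n = 2), WT in blue and spt6-1 in orange. The spt6 sense values fell from a mean of 63.5 to 10.5 RPKM while its antisense values rose from 0.0447 to 38.0 RPKM.

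On the sense strand 1426 of 6547 tested features were higher in spt6-1 and 437 were lower. The largest rises among protein-coding genes were mostly at the chromosome ends. SPAC750.08c (chromosome I, 5578447 to 5579133) went from 12.1 ± 15.3 to 630 ± 89.9 RPKM (97.3-fold, adjusted p 0.00477), and its log2 change was 8.47 without WT replicate 1 and 4.74 without WT replicate 2. SPAC977.18, SPAC212.12, SPAC750.07c, SPBPB2B2.18, SPAC212.08c, SPAC212.06c and ftm7 rose by 33.7-fold to 61.0-fold, and like SPAC750.08c each has a near-identical copy of at least 75.3% of its length elsewhere in the genome, so its reads cannot be placed with certainty. Without WT replicate 1 or WT replicate 2 the log2 changes were 6.57 and 5.29 for both SPAC212.12 and SPAC750.07c, and 5.86 and 4.43 for SPAC212.06c. In WT replicates 1 and 2 and spt6-1 replicates 1 and 2, SPAC212.12 had 50, 8, 1664 and 1101 sense reads. SPAC750.07c had 50, 8, 1664 and 1099, so these genes are not shown to be separate measurements. Among the 10 largest rises, meu7 and isp3 have sequences found once. The meiotically induced gene meu7 (chromosome II, 4272341 to 4274665) rose from 2.68 ± 0.213 to 146 ± 35.2 RPKM (45.4-fold, adjusted p 6.35e-05). The spore coat gene isp3 (chromosome I, 95961 to 96966) rose from 5.55 ± 0.569 to 248 ± 22.1 RPKM (41.1-fold, adjusted p 5.87e-05).

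The largest falls were smaller in size than the largest rises. Besides spt6, SPAC2H10.01 fell from 47.7 ± 18.6 to 8.29 ± 0.917 RPKM (adjusted p 0.00151). The gene psf3, which encodes a subunit of the GINS replication complex, fell from 33.4 ± 0.158 to 6.85 ± 0.804 RPKM (4.62-fold, adjusted p 3.19e-04). The peroxisomal import receptor gene pex7 fell from 575 ± 115 to 143 ± 9.54 RPKM (3.96-fold, adjusted p 0.00313). The endoplasmic reticulum oxidase gene ero11 fell from 96.9 ± 4.74 to 26.5 ± 2.41 RPKM (3.61-fold, adjusted p 0.00107). The genes iah1, izh2, dut1, dtd1 and SPAC23C4.04c fell by 3.70-fold to 3.95-fold, and of these dut1 lost its call without WT replicate 1 (adjusted p 0.0601) and had a log2 change of -1.29 without spt6-1 replicate 1 and -2.65 without spt6-1 replicate 2.

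The median sense change was 0.16 on the log2 scale over all features and 0.03 over protein-coding genes, of which 610 were higher and 415 lower out of 5060. Relative to the median feature the counts were 1206 higher and 727 lower, and after quantile normalization 801 higher and 998 lower. For protein-coding genes these splits were 471 and 684, and 360 and 807. Without spt6-1 replicate 1 there were 914 higher and 171 lower, and without WT replicate 1 there were 970 and 196. The count of lower features was 232 without WT replicate 2 and 199 without spt6-1 replicate 2.

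**Figure D2:**
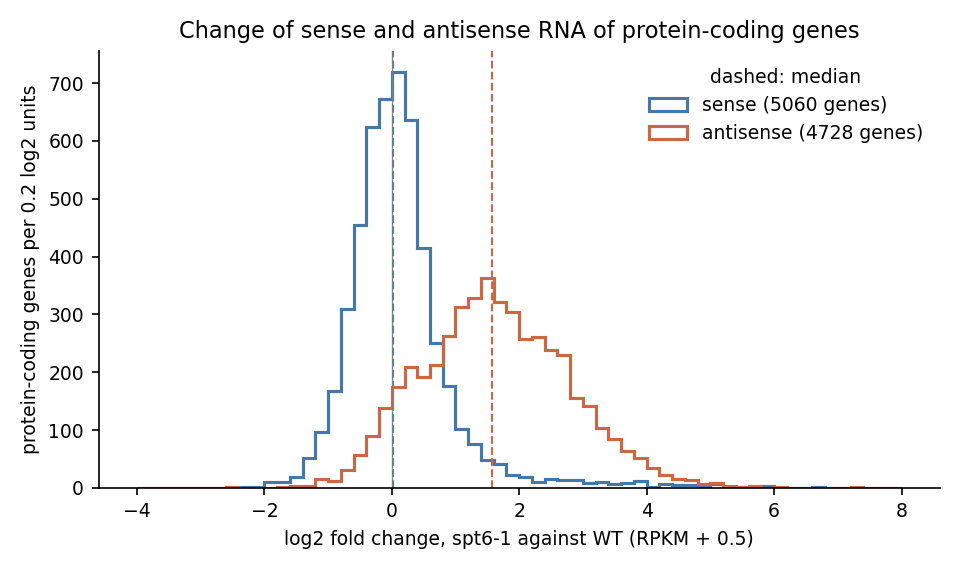
Number of protein-coding genes per 0.2 log2 units of change in spt6-1 against WT, for sense RNA (blue, 5060 genes) and antisense RNA (orange, 4728 genes), with the medians as dashed lines. The sense median lies at 0.03 and the antisense median at 1.58.

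Most of the surplus of higher features came from non-coding RNAs, of which 760 of 1315 rose and 19 fell (camera adjusted p 2.66e-25, adjusted p = 0.0613 with an estimated correlation). Adjusted over the list alone, 830 rose and 36 fell, and after quantile normalization the split was 412 and 183. SPNCRNA.371 (chromosome II, 1636393 to 1636776) rose from 0.659 ± 0.504 to 257 ± 82.4 RPKM (227-fold), and SPNCRNA.234 (chromosome I, 3786105 to 3787136) from 1.69 ± 1.04 to 352 ± 41.4 RPKM (170-fold), both in sequence with near-identical copies over 100% of its length. SPNCRNA.1529, which lies opposite the origin recognition gene orc1 over 2025 bp (chromosome II, 2571145 to 2573169), rose from 2.05 ± 1.03 to 409 ± 76.5 RPKM (166-fold). Each of these 3 had an adjusted p of 6.68e-05. Of the non-coding RNAs that overlap only an opposite-strand coding gene, 500 of 758 rose, against 135 of 288 that overlap no coding gene and 40 of 126 that overlap only a same-strand coding gene.

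Of 45 snoRNAs 29 rose and 2 fell (camera adjusted p 8.40e-05, adjusted p = 0.148 with an estimated correlation), with 14 and 5 after quantile normalization. Of 7 snRNAs 6 rose (0.00161, adjusted p = 0.346 with an estimated correlation). Of 28 pseudogenes 13 rose (0.00189, adjusted p = 0.23 with an estimated correlation), with 9 higher and 1 lower after quantile normalization. Of 46 tRNAs 8 rose (0.0284, adjusted p = 0.671 with an estimated correlation), with 3 higher and 1 lower after quantile normalization, and the call ended without WT replicate 2 (adjusted p 0.609) and without spt6-1 replicate 1 (adjusted p 0.818). For rRNA 0 of 46 features were higher and 1 was lower by limma (0 and 1 at an unadjusted p under 0.05, and 0 and 0 by voom), with a median log2 change of 2.52 that was -0.55 without spt6-1 replicate 1, while 37 were higher without spt6-1 replicate 2. These RNAs mostly lack poly(A) tails, and small rRNA differed by a median of 69.4 times between the spt6-1 libraries. Without spt6-1 replicate 1, the library with more small rRNA, 19 snoRNAs rose and 2 fell (3.33e-05) and 4 snRNAs rose (0.00119), both classes that did not pass with an estimated correlation.

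Camera set each list against all features, and protein-coding genes as a class were themselves placed below the other features (adjusted p 2.66e-25, adjusted p = 0.0613 with an estimated correlation), because non-coding RNAs rose. Lists lower by camera, and others whose call differed, were therefore also set against protein-coding genes only, an alternative chosen after seeing the data. Several of the gene lists fixed in advance held members that rose. Of 11 histone genes 8 rose and 0 fell, and 10 rose adjusted over the list alone (camera adjusted p 0.00371, adjusted p = 0.668 with an estimated correlation). The H2B gene htb1 went from 492 ± 12.2 to 1835 ± 132 RPKM (3.73-fold, adjusted p 0.00629) and the H4 gene hhf2 from 274 ± 69.9 to 928 ± 23.4 RPKM (3.44-fold), while hta1 rose 3.43-fold and hhf1 3.15-fold. Without WT replicate 1 limma called 0 of the 11 (adjusted p 0.0503 for htb1, 0.0628 for hhf2, 0.0846 for hta1 and 0.0733 for hhf1, while camera gave 0.023), and without WT replicate 2 it called 3 (0.0536 for htb1 and 0.0542 for hhf1).

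Of 24 meiotic genes, normally off in dividing cells, 14 rose and 0 fell, and 16 rose adjusted over the list alone (camera adjusted p 5.43e-05, adjusted p = 0.668 with an estimated correlation). Beside isp3, the septin gene spn6 rose 14.8-fold (1.13 ± 0.191 to 23.9 ± 5.31 RPKM), the recombinase gene dmc1 7.63-fold (1.18 ± 0.192 to 12.3 ± 1.05 RPKM) and the linear element gene rec10 from 2.76 ± 0.571 to 13.2 ± 0.25 RPKM. After quantile normalization 7 were higher and 1 lower. Of 13 genes repressed by glucose or encoding hexose transporters 9 rose and 0 fell, and 11 rose adjusted over the list alone (camera adjusted p 2.36e-04, adjusted p = 0.668 with an estimated correlation). The invertase gene inv1 rose 13.4-fold (1.78 ± 0.0976 to 30.0 ± 0.533 RPKM, adjusted p 6.68e-05). The transporter genes ght3 and ght7, both subtelomeric, rose 11.2-fold and 9.96-fold, and the glycerol dehydrogenase gene gld1 rose 6.98-fold. There were 6 higher without WT replicate 1 and 6 without spt6-1 replicate 1, and the log2 change of gld1 was 2.19 without spt6-1 replicate 1 and 3.42 without spt6-1 replicate 2.

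Both groups were at 37 °C, and chaperone and stress genes still differed between them. Of 16 heat shock chaperone genes 5 rose and 0 fell, also adjusted over the list alone (camera adjusted p 0.0416, adjusted p = 0.676 with an estimated correlation). The disaggregase gene hsp104 rose 5.31-fold (81.0 ± 12 to 430 ± 9.21 RPKM, adjusted p 8.93e-04), the Hsp70 gene ssa1 10.2-fold (236 ± 12.3 to 2552 ± 1140 RPKM) and hsp78 rose from 71.4 ± 10.5 to 273 ± 41.9 RPKM. Of 21 core stress genes 8 rose and 0 fell, and 10 rose adjusted over the list alone (camera adjusted p 0.0386, adjusted p = 0.676 with an estimated correlation), among them the transcription factor gene atf1 (2.78-fold), the sulfiredoxin gene srx1 (2.86-fold) and the catalase gene ctt1 (72.5 ± 5.12 to 251 ± 92.9 RPKM). The list call of the chaperones ended without WT replicate 1 (adjusted p 0.103, 4 higher), WT replicate 2 (0.171, 3 higher) or spt6-1 replicate 1 (0.0737, 4 higher). That of the stress genes ended without WT replicate 1 (0.103, 4 higher) or spt6-1 replicate 1 (0.148, 4 higher and 1 lower), and 5 stress genes were higher after quantile normalization.

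Genes of ribosome production were lower as groups. Of 131 cytosolic ribosomal protein genes 13 fell and 0 rose, and 0 passed when adjusted over the list alone (camera adjusted p 1.75e-11, adjusted p = 0.668 with an estimated correlation). The median member changed by -0.59 on the log2 scale, and rps2401 (553 ± 2.75 to 254 ± 10 RPKM) and rps2802 (579 ± 139 to 213 ± 21.3 RPKM) were among those past the threshold, and 31 members were lower at an unadjusted p under 0.05 and 23 by voom. Of 69 ribosome biogenesis genes 10 fell and 0 rose, with 4 lower when adjusted over the list alone (camera adjusted p 9.73e-07, adjusted p = 0.668 with an estimated correlation), such as rrp8 (15.3 ± 0.269 to 7.89 ± 0.0567 RPKM) and utp14 (52.9 ± 0.574 to 28.0 ± 2.35 RPKM). With WT replicate 1, WT replicate 2, spt6-1 replicate 1 or spt6-1 replicate 2 left out, 0, 4, 1 and 4 ribosomal protein genes and 1, 5, 1 and 2 biogenesis genes were lower, while camera passed for both lists each time. Against protein-coding genes only both lists passed as well (4.51e-09 and 1.46e-04, adjusted p = 0.627 with an estimated correlation). The gene rps2802 lost its call without WT replicate 1 (adjusted p 0.0757) or spt6-1 replicate 2 (0.0566), rrp8 without spt6-1 replicate 1 (0.0508), and rps2401 (0.066 to 0.0926) and utp14 (0.0513 to 0.0771) without any of the 4.

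Lists of RNA processing and heterochromatin factors held a few members that fell. Against protein-coding genes only, camera placed the splicing (0.0475, adjusted p = 0.727 with an estimated correlation) and decay lists (0.0279, adjusted p = 0.705 with an estimated correlation) lower, while the RNAi list did not pass (0.0802), so its call against all features is not evidence of a fall as a group. Of 20 splicing factors 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p 0.0106, adjusted p = 0.676 with an estimated correlation), namely the genes of the splicing proteins prp1 (17.1 ± 2.24 to 7.79 ± 1.09 RPKM), prp16 (2.14-fold) and cdc28 (1.62-fold). Of 23 RNA decay and surveillance genes 2 fell and 0 rose, with 0 when adjusted over the list alone (camera adjusted p 0.00371, adjusted p = 0.668 with an estimated correlation), the exosome nuclease gene dis3 (1.85-fold) and the helicase gene mtr4 (1.67-fold). Of 20 RNAi and heterochromatin genes 3 fell and 0 rose, with 2 when adjusted over the list alone (camera adjusted p 0.018, adjusted p = 0.668 with an estimated correlation), the genes chp1 (1.94-fold), arb1 (1.79-fold) and stc1 (1.57-fold). The splicing call ended without WT replicate 1 (adjusted p 0.099, 1 lower) and the RNAi call without spt6-1 replicate 2 (adjusted p 0.0503, 0 lower), and with the libraries left out in the same order as above 1, 2, 2 and 0 splicing, 0, 1, 0 and 0 decay, and 1, 0, 1 and 0 RNAi genes were lower. Among the named genes, prp1 lost its call without spt6-1 replicate 2 (0.0506), prp16 without WT replicate 1 (0.0635) or spt6-1 replicate 2 (0.0544), dis3 without WT replicate 1 (0.139) or either spt6-1 replicate (0.0703 and 0.144), arb1 without WT replicate 2 (0.0653) or either spt6-1 replicate (0.0885 and 0.056), and chp1 without either WT replicate (0.0954 and 0.0544) or spt6-1 replicate 2 (0.0777). The calls of cdc28 (0.059 to 0.131), mtr4 (0.0584 to 0.149) and stc1 (0.0877 to 0.191) ended without any of the 4 libraries, and that of stc1 also with no trend (0.0578) and by voom (0.0602).

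Of 25 elongation factors and partners 3 rose and 2 fell, also adjusted over the list alone. Besides spt6, the list held the ELL complex genes ell1 (49.8 ± 4.59 to 131 ± 14 RPKM, 2.61-fold) and eaf1 (1.72-fold) and the polymerase CTD kinase gene lsk1 (1.74-fold), all 3 higher. Camera placed the list below all other features (adjusted p 0.0323, adjusted p = 0.676 with an estimated correlation) but not below protein-coding genes (0.159), so no fall of the list is claimed. With a library left out, lsk1 passed in none of the 4 fits (adjusted p 0.0584 to 0.0861) and eaf1 lost its call without WT replicate 1 (0.108), spt6-1 replicate 1 (0.104) or spt6-1 replicate 2 (0.0759), and the list call ended without WT replicate 1 (0.103), without spt6-1 replicate 2 (0.097) and after quantile normalization (0.146, 3 higher and 3 lower). Relative to the median feature 3 members were higher and 5 lower.

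The other lists did not pass camera with the settings fixed as main, though some did under alternatives. Of 11 phosphate and thiamine repressed genes 3 rose, also adjusted over the list alone, with nmt1, a thiamine synthesis gene, 10.1-fold higher (0.812 ± 0.0247 to 12.8 ± 1.08 RPKM), the acid phosphatase gene pho1 9.71-fold and the transporter gene tgp1 3.84-fold (camera adjusted p 0.12), and the list passed without WT replicate 2 (0.0271, 5 higher) and after quantile normalization (0.0337), and against protein-coding genes only (0.0133), but not with an estimated correlation (adjusted p = 0.697 against all features and adjusted p = 0.709 against protein-coding genes). The gene pho1 is subtelomeric, and its log2 change was 2.43 without WT replicate 1 and 4.13 without WT replicate 2. Of 11 iron starvation genes 3 rose, and 7 adjusted over the list alone (0.0654), with str3, a transporter gene, from 3.05 ± 0.505 to 24.0 ± 6.38 RPKM, with 1 higher without WT replicate 1, and 1 higher and 1 lower without spt6-1 replicate 1. The iron list passed without WT replicate 2 (0.0253) or spt6-1 replicate 2 (0.0366), with a filter 5 times as strict (0.0445), after quantile normalization (0.0204) and against protein-coding genes only (0.00566), but not with an estimated correlation (adjusted p = 0.697 and adjusted p = 0.709). Of the telomere-linked helicases and silent mating type genes tlh2 rose 33.5-fold (2.13 ± 1.91 to 76.5 ± 20.8 RPKM) and tlh1 32.1-fold, while mat3-Mc had a log2 change of 0.31 with an adjusted p of 0.319 (camera adjusted p 0.0579, with 2 of 3 higher when adjusted over the list alone), and that list passed under 8 alternatives: without WT replicate 1 (0.0188) or WT replicate 2 (0.0253), with a pseudocount of 1 (0.0486), a filter 5 times as strict (0.0445), median-centred libraries (0.0477), quantile normalization (0.0223), a replicate block (0.0359) or protein-coding genes only (0.00604), but not with an estimated correlation (adjusted p = 0.668 and adjusted p = 0.627). The log2 changes without WT replicate 1 or WT replicate 2 were 5.88 and 4.25 for tlh2, and 5.83 and 4.18 for tlh1. Near-identical copies cover 94.1% of tlh2 and 100% of tlh1 and of mat3-Mc, so their reads cannot be placed with certainty. The genes tlh1 and tlh2 are thus not shown to be separate measurements, and the mat3-Mc value cannot be assigned to the silent locus. Of 10 M mating type genes 4 rose and 1 fell, also adjusted over the list alone (0.527), with the M-factor gene mfm3 3.54-fold higher, and 1 rose without WT replicate 1 or spt6-1 replicate 1 and 2 without spt6-1 replicate 2.

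The mating, cell cycle and housekeeping lists did not pass either. Of 4 P mating type genes map2 (2.15-fold, but a log2 change of -0.09 after quantile normalization) and map4 rose, 2 adjusted over the list alone (camera adjusted p 0.806), and limma called neither without WT replicate 1 (0.0943 and 0.19), WT replicate 2 (0.054 and 0.0663) or spt6-1 replicate 1 (0.0643 and 0.206). Without spt6-1 replicate 2 map2 lost its call (0.0507). The call of map4 (adjusted p 0.0487) also ended with a pseudocount of 0.1 (0.0504), no filter (0.0649), median-centred libraries (0.0695), quantile normalization (0.0744), no trend (0.0695) and voom (0.051). After quantile normalization 0 of the 4 were higher and 2 were lower. Of 20 MBF and DNA replication genes 4 rose and 4 fell, also adjusted over the list alone (0.215), among them ctp1 (2.01-fold) and the cohesin gene rad21 (1.89-fold) higher and the cyclin gene cig2 (1.89-fold) lower. These calls ended for ctp1 and rad21 without WT replicate 1 (0.0611 and 0.0737) or spt6-1 replicate 1 (0.0666 and 0.0775), and for cig2 without WT replicate 2 (0.106) or either spt6-1 replicate (0.124 and 0.054). Relative to the median feature 2 were higher and 6 lower, and after quantile normalization 2 and 9. Of 20 histone chaperones and deacetylases 1 fell, 0 adjusted over the list alone (0.12), the deacetylase gene clr6 (1.80-fold), which lost its call without WT replicate 1 (0.118), spt6-1 replicate 1 (0.137) or spt6-1 replicate 2 (0.0587). Of 11 RNA polymerase II subunits rpb7 fell 2.37-fold, also adjusted over the list alone (0.103), but not without spt6-1 replicate 1 (0.0548), and the list passed without spt6-1 replicate 2 (0.0305, adjusted p = 0.668 with an estimated correlation over all libraries). Of 15 glycolysis and cytoskeleton genes 1 rose, 0 adjusted over the list alone (0.892), the gene gpd3 (542 ± 238 to 1733 ± 341 RPKM), which lost its call without WT replicate 2 (0.162) or spt6-1 replicate 1 (0.0861). Of 13 Tf2 retrotransposons 0 rose and 0 fell by limma (camera adjusted p 0.501). There were 0 calls adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by voom. Tf2-7 had a log2 change of 0.32 with an adjusted p of 0.382, and near-identical copies cover 100% of its length. The estimated correlation of the list was 0.997, so the 13 are not shown to be separate measurements. Camera pointed down while the median lay above 0 for the MBF (median 0.06, mean 0.00), histone chaperone (0.04, -0.07), polymerase (0.06, -0.16) and glycolysis lists (0.38, 0.36). None of these 4 passed against protein-coding genes only (0.266 to 0.614), where the glycolysis list pointed up.

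**Figure D3:**
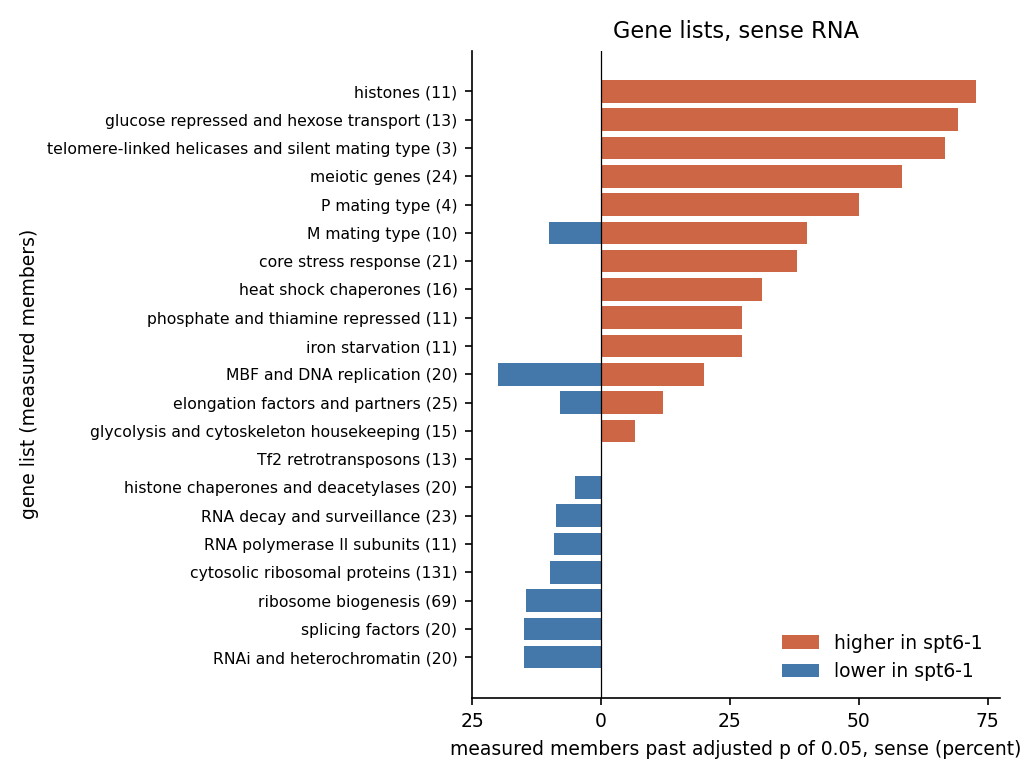
Percent of the measured members of each gene list reported here whose sense RNA was higher (orange, to the right) or lower (blue, to the left) in spt6-1 past an adjusted p of 0.05, with the number of measured members beside the name. Histones (8 of 11 higher) stand at the top, and RNAi and heterochromatin genes (3 of 20 lower) at the bottom.

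Genes near the ends of chromosomes I and II, in regions known for silent chromatin, were higher as a group. Of 121 subtelomeric protein-coding genes 98 rose and 0 fell, with a median log2 change of 2.91 (camera adjusted p 9.11e-24, adjusted p = 0.148 with an estimated correlation). Genes with near-identical copies can share reads, so counts in this paragraph that include them are not all of separate measurements. The telomere-linked helicase gene tlh1 (chromosome I, 1 to 5662) rose from 2.21 ± 1.98 to 76.0 ± 23.7 RPKM with an adjusted p of 7.93e-04. Its log2 change was 5.83 without WT replicate 1 and 4.18 without WT replicate 2, and near-identical copies cover 100% of its length. Within 25 kb of an end 26 of 26 genes rose, with a median log2 change of 4.25, from 25 to 50 kb 35 of 35 rose (3.52), from 50 to 100 kb 37 of 60 rose (1.79), and from 100 to 200 kb 30 of 152 rose and 3 fell (0.12). Of 64 subtelomeric genes with a sequence found once, 49 rose and 0 fell (camera adjusted p 1.45e-14, adjusted p = 0.16 with an estimated correlation). The list members isp3, ght3, ght7, str3, pho1, tlh1 and tlh2 named above are subtelomeric. For them the list and the position cannot be told apart.

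**Figure D4:**
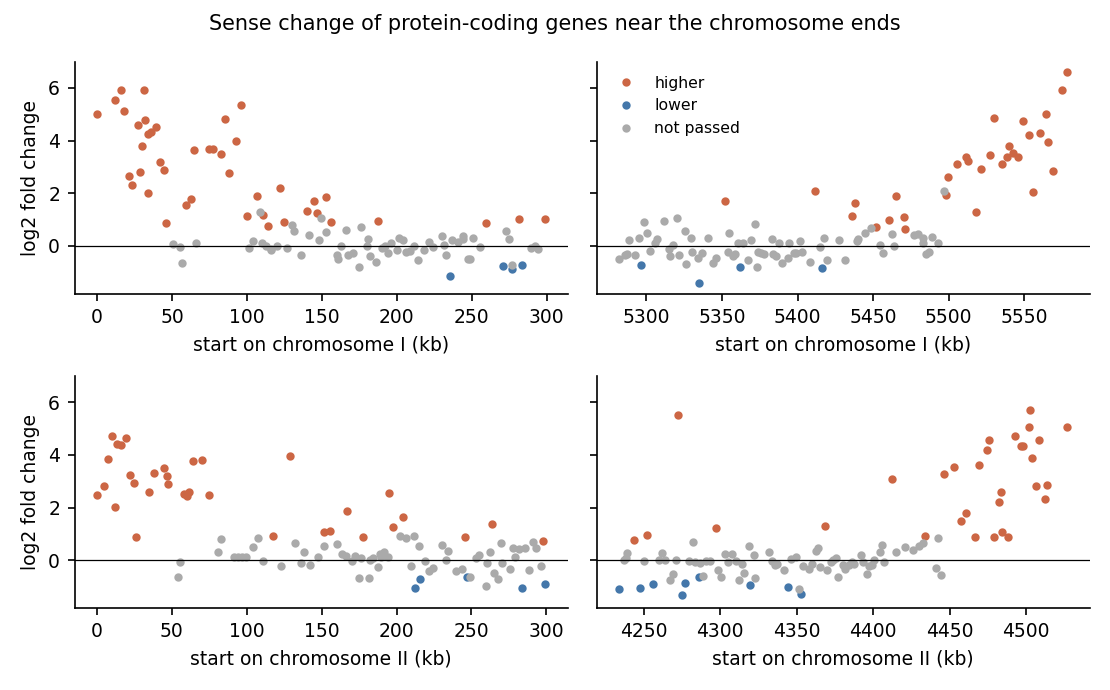
Log2 fold change of sense RNA of each protein-coding gene against its start in kb within 300 kb of the left and right ends of chromosomes I (top) and II (bottom), with a point per gene colored by whether it was higher, lower or did not pass. All 26 genes within 25 kb of an end lie above 0.

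Intron content and the 3' neighbour were not tied to a sense change by camera against protein-coding genes only. Of 2490 intron-containing genes 238 rose and 231 fell, with a median log2 change of -0.01 against 0.07 for genes without introns (0.127). The splits were 166 and 364 relative to the median feature and 120 and 438 after quantile normalization. Of 2774 genes with a convergent neighbour on the 3' side 316 rose and 215 fell, with a median of 0.05 against 0.01 for tandem neighbours (0.742). Against all features camera placed both classes lower (2.40e-06 and 4.68e-04, adjusted p = 0.0613 and adjusted p = 0.148 with an estimated correlation), as it did protein-coding genes as a whole, so these values do not test introns or neighbours. The splits of the convergent genes were 253 and 357 relative to the median feature and 191 and 417 after quantile normalization.

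Antisense RNA rose at most protein-coding genes. Of 4728 tested genes 3872 were higher in spt6-1 and 78 lower, and the median gene rose by 1.58 on the log2 scale, or 2.99-fold, a size that depends on the pseudocount (2.3 on the log2 scale with 0.1, 1.21 with 1, and 2.54 by voom). With the pseudocount of 0.5 the largest rise was at orc1 (SPBC29A10.15, chromosome II, 2571077 to 2573477), where SPNCRNA.1529 is annotated. It went from 1.78 ± 0.876 to 354 ± 67.5 RPKM (160-fold, adjusted p 6.57e-07). The sense RNA of orc1 was 1.70-fold higher (adjusted p 0.0279), a call that ended without any of the 4 libraries (0.0687 to 0.121) and under both other scalings (0.0649 and 0.0558). The actin-related protein gene alp5, with no annotated opposite-strand feature, rose from 0.969 ± 0.23 to 72.2 ± 9.04 RPKM (49.6-fold), and the chromatin remodeler gene hrp1 from 0.667 ± 0.0116 to 47.0 ± 0.757 RPKM (40.7-fold). The ubiquitin-conjugating enzyme gene ubc4 rose 42.9-fold on the antisense strand, while its sense RNA went from 1328 ± 21.7 to 709 ± 28.4 RPKM with an adjusted p of 0.0789 (0.0425 relative to the median feature, 0.0194 with no trend and 0.0352 by voom). SPAC186.07c, tlh1, tlh2, the TFIIIB gene bdp1 and ftm2 rose by 42.1-fold to 53.9-fold. Near-identical copies cover at least 94.1% of tlh1, tlh2 and ftm2, so their reads cannot be placed with certainty.

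A few genes lost antisense RNA. Of 2861 tested genes with an annotated opposite-strand feature 69 fell, against 9 of 1867 without one. Among the genes named in this paragraph only ght5 overlaps no such feature. A fall can thus be lower RNA of the annotated opposite feature, which was not tested. SPAC56F8.12 (chromosome I, 1146833 to 1148085) fell from 63.8 ± 7.74 to 10.8 ± 1.08 RPKM (5.67-fold, adjusted p 3.8e-06), and its sense RNA was 4.09-fold higher (adjusted p 0.00573, but 0.193 after quantile normalization). The cell fusion gene prm1 fell from 103 ± 19.9 to 41.7 ± 5.41 RPKM (2.45-fold) and the high-affinity glucose transporter gene ght5 2.92-fold. The genes mug74, SPAC9G1.14, psu2, SPCC576.17c, SPAC1071.09c, pus3 and akr7 fell by 2.26-fold to 3.43-fold, and of these SPAC9G1.14 lost its call without spt6-1 replicate 2 (log2 change -0.93, adjusted p 0.177) and changed by -2.59 without spt6-1 replicate 1. The count of genes that fell was 41 without spt6-1 replicate 2.

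Relative to the median gene, 1570 genes gained more antisense RNA and 1534 gained less or lost it, and after quantile normalization the split was 1316 and 1494. Among genes with no annotated opposite-strand feature, an alternative chosen after seeing the data, 1774 of 1867 were higher and 8 lower. Subtelomeric genes gained more than others, with 111 of 114 higher and a median of 2.39 (camera adjusted p 3.82e-05, adjusted p = 0.514 with an estimated correlation), or 70 higher and 11 lower relative to the median gene. Single-copy subtelomeric genes gave 58 of 61 higher (0.0123, adjusted p = 0.514 with an estimated correlation). Genes with a convergent neighbour gained less, 1972 of 2586 higher and 55 lower, with a median of 1.39 against 1.80 for tandem neighbours (camera adjusted p 0.00101, adjusted p = 0.514 with an estimated correlation). Intron-containing genes had a median of 1.5 against 1.67 for those without introns (camera adjusted p 0.294).

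Of the lists, 3 differed from other genes in antisense change by camera, each with an adjusted p = 0.716 with an estimated correlation. Of 101 ribosomal protein genes 100 rose, with rpl102 13.0-fold higher, and the list rose more than other genes (adjusted p 0.0461). That call ended under 8 alternatives, such as without WT replicate 1 (0.0974), without WT replicate 2 (0.145) and relative to the median gene (0.255). Of 13 glucose repressed and hexose transport genes 8 rose and 2 fell, less than other genes (adjusted p 0.00617), with ght7 22.3-fold and ght3 10.9-fold higher, and the call ended relative to the median gene (0.0672) and after quantile normalization (0.0696). Of 4 P mating type genes only map1 rose (1.53-fold), less than other genes (adjusted p 0.016), a call that ended with a filter 5 times as strict (0.19) and after quantile normalization (0.0919), and map1 passed in none of the fits with a library left out (adjusted p 0.057 to 0.2), with a log2 change of -0.98 relative to the median gene. Relative to the median gene 3 lists had 29 higher and 17 lower, 2 and 7, and 0 and 4, in the order given.

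The remaining lists did not pass camera. For each, the count of higher genes is followed by the split relative to the median gene. Of 68 ribosome biogenesis genes 62 rose (37 higher and 10 lower), with nop14 37.8-fold and utp18 21.6-fold higher, and of 23 RNA decay genes 22 rose (15 and 2), with cid14 16.9-fold and upf1 14.5-fold higher. Of 20 splicing factors 19 rose and 1 fell (10 and 4), with prp16 28.8-fold and prp1 24.4-fold higher, and of 20 RNAi and heterochromatin genes 18 rose (9 and 4), with the Argonaute gene ago1 18.1-fold higher. Of 24 elongation factors 21 rose (13 and 4), with the histone methyltransferase gene set2 14.4-fold and hrp3 11.8-fold higher, and of 20 histone chaperones and deacetylases 18 rose (10 and 5), with cph2 15.6-fold higher. Of 10 polymerase subunits 8 rose (3 and 4), with rpb2 16.7-fold and rpb1 11.3-fold higher. Of 11 Tf2 elements 11 rose (11 and 0), with Tf2-8 at 1.72 ± 0.0725 and 12.3 ± 1.96 RPKM, but each has near-identical copies over 100% of its length (estimated correlation 0.922), so the 11 are not separate measurements. Of 8 histone genes 5 rose and 2 fell (0 and 3), with pht1 3.71-fold higher, although it lost its call relative to the median gene (0.285) and its log2 change was -0.09 after quantile normalization.

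Among stress genes, 12 of 16 rose and 1 fell (3 higher and 8 lower relative to the median gene), with pyp2 rising from 0.201 ± 0.00611 to 9.98 ± 0.642 RPKM, and 7 of 8 chaperone genes rose (1 and 3), with psi1 4.14-fold higher, a call that ended after quantile normalization (log2 change 0.25, adjusted p 0.246). Of 27 meiotic genes 19 rose (5 and 16), with rec10 5.61-fold higher, and of 7 M mating type genes 4 rose (1 and 5), with mam1 7.99-fold higher. Of 10 phosphate and thiamine genes 8 rose (1 and 5), with thi5 13.0-fold higher, and of 11 iron genes 8 rose (3 and 5), with str3 8.13-fold higher. Of 19 MBF and DNA replication genes 11 rose (3 and 10), with res2 9.82-fold higher. Of 4 glycolysis and cytoskeleton genes 4 rose (2 and 1), with nda2 from 0.0536 ± 0.0311 to 9.93 ± 0.624 RPKM. The 3 telomere-linked and silent mating type genes all rose (2 and 1), but tlh1 and tlh2 have near-identical copies and are not shown to be separate measurements. Adjusted over the list alone, the counts of higher and lower genes were the same except for the chaperone and deacetylase list (19 higher), the meiotic list (18 higher), the glucose list (1 lower) and the P mating type list (0 higher). Camera adjusted p-values of these lists ran from 0.0521 to 0.983. The lists for RNA decay (0.0118), Tf2 elements (0.0118), ribosome biogenesis (0.0118) and elongation factors (0.0473) passed relative to the median gene, each with more gain than other genes, and none passed with an estimated correlation (adjusted p = 0.716). These 4 also passed after quantile normalization (0.0241, 0.00545, 0.0173 and 0.0241). Without WT replicate 1 or WT replicate 2 the lists for RNA decay (0.0498 and 0.0288), Tf2 elements (0.042 and 0.0101) and ribosome biogenesis (0.042 and 0.0101) passed, as they did with no filter (0.0405, 0.0405 and 0.0252). Ribosome biogenesis also passed with a pseudocount of 0.1 (0.0404), and the histone list passed with no filter (0.00444, adjusted p = 0.716 with an estimated correlation), with less gain than other genes.

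The ratio of antisense to sense RNA rose at 3355 of 4682 genes and fell at 283. The largest rises were at spt6 (8.63 on the log2 scale, adjusted p 2.27e-07), orc1 (6.56), ubc4 (6.33), the ribosome biogenesis gene utp14 (from -6.38 to -0.27) and alp5 (from -5.39 to 0.70). The largest falls were at SPAC9G1.14 (-6.80), the cation transporter gene cta3 (-5.49), meu7 (-4.94), inv1 (-4.28) and spn6 (-3.64). All 10 passed with each library left out, and cta3 had a log2 change of -4.57 without spt6-1 replicate 1 and -6.40 without spt6-1 replicate 2. Relative to the median gene 1336 ratios were higher and 1369 lower, and after quantile normalization 1243 and 1257. The size of some ratio changes depends on the pseudocount. With 0.1 and 1 they were 10.586 and 7.658 for spt6, 7.497 and 5.295 for utp14, and -6.233 and -4.89 for cta3. With the pseudocount of 0.5 the sense log2 changes of meu7, inv1 and spn6 were 5.51, 3.75 and 3.89. The antisense log2 change of SPAC9G1.14 was -1.76. Most of the ratio fall at meu7, inv1, spn6 and SPAC9G1.14 thus came from higher sense RNA, not from lower antisense RNA.

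Sense and antisense changes were weakly and inversely related by rank. Across 4682 genes, which are not independent replicates, the sense and antisense log2 changes had a Spearman rho of -0.212 and a Pearson r of -0.12, the only relation of this kind computed between the strands. Sense was lower and antisense higher at 46.8% of the genes, and both were higher at 45.8%. With sense and antisense taken from different libraries rho was -0.178 and -0.222, and within replicate 1 and replicate 2 it was -0.168 and -0.213. The Pearson r was -0.014 over genes with no opposite-strand feature and -0.263 without subtelomeric genes, so the linear relation depends on the set of genes.

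Antisense RNA made up 4.13% ± 0.07 of the RPKM of protein-coding genes in WT and 6.93% ± 0.26 in spt6-1 (SD, n = 2 each, exact permutation p = 0.33, the smallest that 2 against 2 libraries can give). Both spt6-1 libraries (6.75% and 7.12%) lay above both WT libraries (4.08% and 4.18%). The median gene's share was 1.68% ± 0.16 in WT and 11.9% ± 0.9 in spt6-1.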

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

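Voom on the recovered reads, protein-coding genes only, genes with no annotated opposite-strand feature, antisense values scaled by the median sense change, single-copy subtelomeric genes and the correlation without subtelomeric genes were chosen after seeing the data. The spt6 sense fall, antisense rise and ratio rise kept their direction and their side of the threshold under each alternative run, with sense log2 changes of -2.88 to -2.28. Of the sense calls, 1237 of 1863 were also calls of the same sign after quantile normalization, and 0 calls had the opposite sign under any alternative. On the antisense strand, median-centred libraries gave 689 calls of the opposite sign and quantile normalization 817, because both settings remove the shift of the median gene by construction.

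Sense counts that differed from the 1426 higher and 437 lower were 727 lower with median-centred libraries, 801 higher and 998 lower after quantile normalization, 1120 changed and 669 higher with protein-coding genes only (fewer features tested), and 193 lower at a fold change of at least 2. With a library left out, which lowers the number of samples, 1085 to 1389 changed, 914 to 1163 were higher and 171 to 232 lower. Antisense counts were 2437 changed and 2367 higher with a filter 5 times as strict (fewer genes tested), 1570 higher and 1534 lower with median-centred libraries, 1316 and 1494 after quantile normalization, 1782 changed, 1774 higher and 8 lower with no opposite-strand feature (fewer genes tested), and 24 lower at a fold change of at least 2. With a library left out 41 to 67 were lower. Voom on the recovered reads gave 1436 higher and 449 lower sense features and 3865 and 84 antisense genes, and scaling by the median sense change gave 3861 and 87. Ratio counts were 2276 changed, 2100 higher and 176 lower with the strict filter, 1336 and 1369 with median-centred libraries, and 1243 and 1257 after quantile normalization.

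With an estimated correlation 0 of the gene lists passed camera on either strand. That version was stricter even where the estimate lay near or below the preset 0.01. On the sense strand the unadjusted camera p of histones (estimate 0.014) was 9.63e-04 preset and 0.0832 estimated. For meiotic genes (-0.033) it was 7.4e-06 and 0.0381. The other lists that passed on the sense strand had higher estimates, from 0.073 (ribosome biogenesis) to 0.481 (splicing factors). For these the preset of 0.01 assumes less correlation than was estimated. With 4 libraries few degrees of freedom are left, so these failures cannot separate correlated genes from too few samples. Against protein-coding genes only, chosen after seeing the data, the elongation (0.159) and RNAi lists (0.0802) lost their sense calls, and the telomere-linked, phosphate and iron lists gained one (0.00604, 0.0133 and 0.00566). Of the 3 lists that passed on the antisense strand, the number became 6 with no filter, 1 with the strict filter, 5 with median-centred libraries and 3 to 5 with a library left out. Higher non-coding RNAs numbered 412 after quantile normalization, and single-copy subtelomeric genes 49. The correlation of sense and antisense changes was -0.178 with sense from replicate 1 and antisense from replicate 2, -0.249 without subtelomeric genes and -0.156 with no opposite-strand feature. The median within 25 kb of a chromosome end was 5.16 with a pseudocount of 0.1, 3.76 with 1, 4.36 with the strict filter, 4.09 with median-centred libraries, 3.57 after quantile normalization and 3.97 to 4.54 with a library left out. The difference in antisense share was 10.24 points for the median per gene. Log2 changes that turned were -0.094 for map2 (sense) and -0.09 for pht1 (antisense) after quantile normalization, and -0.98 with median-centred libraries and -1.32 after quantile normalization for map1 (antisense). Except where stated, the cause was not tested.

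The fold moved by over 1.5 times with a pseudocount of 0.1 for 6 of 83 sense changes and 33 of 50 antisense changes recomputed gene by gene, and with 1 for 3 and 29, because WT antisense values lie near 0. Of these calls 1 sense call and 0 antisense calls ended with a pseudocount of 0.1. The median antisense change was 2.3 with a pseudocount of 0.1, 1.21 with 1 and 2.54 by voom.

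A replicate block gave 2210 sense, 4068 antisense and 3820 ratio calls, and 0 calls of the opposite sign. The deviations of libraries with the same number correlated at 0.323 for sense and 0.202 for antisense RNA. A read per kilobase equals 0.0278 to 0.0581 RPKM, so low antisense values in WT rest on few reads. In simulated data 57.3% of 2-fold sense changes were recovered, so smaller changes can be missed, though the simulation changed far fewer genes than the data show.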

Other observations

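The comparisons of centromeric RNAs and of symbol families, and the tests of overlapping opposite-strand genes, DNA as the only source, shared copies, poorer alignment of the mutant allele and convergent read-through as the only source, were chosen only after the result was seen. Many measured RNAs of the centromeres were higher in spt6-1. Of 112 such RNAs in the reference only 26 are in the table, of which 16 passed the filter and had a median log2 change of 5.26 (1.65 to 7.83), but only 1 of these reached the filter in both WT libraries, so the filter itself favours rises. With no filter, 20 with reads were tested, and 16 were higher and 0 lower by limma. Beside SPNCRNA.371 and SPNCRNA.234, SPNCRNA.231 went from a mean of 1.33 to 142 ± 11.5 RPKM (78.9-fold, adjusted p 5.87e-05), nam5 from 0.158 to 24.6 ± 6.96 RPKM (37.4-fold) and nam6 rose 39.7-fold (n = 2 per group). All 16 have near-identical copies over more than 50% of their length, so the reads cannot be assigned to a single repeat.

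Gene families sharing a symbol were also compared, 51 in all, of which 17 passed camera against all features (15 lower) and 12 against protein-coding genes only (8 lower and 4 higher), and 5 are given here. With an estimated correlation against protein-coding genes these 5 did not pass (adjusted p = 0.718). Of 18 meu genes, found through their meiotic expression, 10 rose and 0 fell (camera adjusted p 0.00239, adjusted p = 0.579 with an estimated correlation, and 4.73e-06 against protein-coding genes only), with 6 higher and 2 lower after quantile normalization. Of 20 wtf genes, known as meiotic drivers, 9 rose (0.0128, adjusted p = 0.688 with an estimated correlation, and 2.25e-04), with 6 higher with median-centred libraries and 1 after quantile normalization. Of 19 trm genes, most of which encode tRNA modification enzymes, 5 fell (8.79e-04, adjusted p = 0.579 with an estimated correlation, and 0.00497). Of 26 tif genes for translation initiation factors 4 fell (0.00239, adjusted p = 0.579 with an estimated correlation, and 0.0218). Of 111 mug genes 34 rose and 9 fell (0.14, adjusted p = 0.688 with an estimated correlation, and 7.35e-04), with 26 and 11 with median-centred libraries and 12 and 23 after quantile normalization.

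Antisense RNA rose at most protein-coding genes. In the 100 most abundant genes with no opposite-strand feature, the antisense RPKM was 0.0538% and 0.0594% of sense in spt6-1, while the median gene would need 10.2% and 8.47%, which argues against a loss of strand specificity. In genes with no annotated opposite-strand feature the median gain was 1.98, above the 1.26 of other genes. This argues against reads of annotated features that overlap the gene as the only source. In spt6-1 replicates 1 and 2 the medians were 2.08 and 1.89, against 1.33 and 1.20 for other genes. The 5 and 95 percent bounds from resampling genes (1.94 to 2.02) leave out this spread between libraries. Reads running on from a neighbour that does not overlap the gene are not covered by this comparison. DNA as the only source would add an even amount to each gene, but the gain at the 90th percentile was 27.1 and 35.3 times that at the 10th. A smaller even share from DNA cannot be told apart, since the 10th percentile of the gain was 0.149 and 0.12 of the median gain and no table separates it from RNA.

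Sense RNA of subtelomeric genes rose. Of 64 subtelomeric genes with a sequence found once 49 rose, which argues against reads shared between copies as the whole cause. Genomic DNA would raise silent genes alike everywhere, but the median gain of 55 silent subtelomeric genes was 11.9 and 7.99 times that of 189 silent genes elsewhere in the 2 spt6-1 libraries. With both technical explanations tested here argued against, a loss of silencing near chromosome ends in spt6-1 is a hypothesis from the same data, and no test here addressed silencing.

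At spt6 the sense RNA fell and the antisense RNA rose. Poorer alignment of reads from the mutant allele was predicted to lower both strands, but antisense RNA rose by 6.06 on the log2 scale. This cannot decide the question, since antisense RNA rose at 3872 of 4728 genes and a rise would still show if part of the reads were lost. A share of poorer alignment in the sense fall was left open. A further change of the strain at this locus cannot be told apart, since it goes with the genotype in both libraries. The neighbouring gene has1 had a sense log2 change of -0.84 (adjusted p 0.0542) and mrc1 one of -0.25 (0.328), and a neighbour passed in 3 of the 13 fits (adjusted p 0.0259 to 0.213). With the pseudocount of 0.5 the antisense rise at spt6 was second in rank to that at orc1 (7.32). The size at spt6 was 7.97 with a pseudocount of 0.1 and 5.145 with 1, so this rank depends on the pseudocount.

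A hypothesis that longer genes gain more antisense RNA was left open, with a Spearman rho of 0.108 between length and change (0.122 and 0.09 in the spt6-1 libraries). Read-through from the convergent neighbour as the only source of the antisense gain was argued against, since genes with a tandem 3' neighbour gained a median of 1.80 against 1.39 for those with a convergent one. In spt6-1 replicates 1 and 2 these medians were 1.89 and 1.72, against 1.47 and 1.31. Bounds from resampling genes (1.73 to 1.85 for tandem neighbours) leave out this spread. A hypothesis that such read-through adds to differences between genes with a convergent neighbour was left open, with a rho of 0.143 over 2566 genes. Of 901 non-coding RNAs opposite a coding gene 585 rose (64.9%), against 46.9% of those that overlap no coding gene, a difference of 18.1 points. This met the prediction of a hypothesis that the rising RNAs are antisense partners of coding genes. It is no independent support, since reads of such an RNA are also counted as antisense reads of the gene. In the spt6-1 libraries SPNCRNA.1529 had 26274 and 12427 sense reads, and orc1 27005 and 12706 antisense reads.

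Ribosomal RNA differed between the spt6-1 libraries. For 33 rRNA features shorter than 200 nt, the level in replicate 1 was a median of 69.4 times that in replicate 2 (0.758 to 208), against 1.3 for the WT replicates. In spt6-1 replicate 2 rRNA took 3.73% of the sense reads, below the 12.75% and 6.43% of WT, while snoRNAs took 0.11% against 0.02% in both WT libraries. A general excess of RNA without poly(A) tails, judged by rRNA alone, thus does not explain the snoRNA rise in that library. For snoRNAs in spt6-1 replicate 1, and for snRNAs, at most 0.01% of the sense reads, it stays open. The tRNA call ended without spt6-1 replicate 1 (0.818), so for tRNAs a difference in poly(A) selection stays open. SPRRNA.10 had 262 and 231 RPKM in WT and 13100 and 182 RPKM in spt6-1.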
